A study of Homo sapiens with 6 samples.

How the data were processed

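RNA was measured by single-end RNA-seq in 6 libraries of Calu-3 cells, 3 transfected with negative control siRNA (siNC) and 3 with siRNA against KLF5 (siKLF5). Each siRNA was used at 20 nmol with a lipid reagent, and total RNA was extracted with TRIzol, per the labels' protocols. Libraries were made with the TruSeq RNA kit version 2, per the labels. This kit does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. The submitters' processing notes name STAR 2.6, featureCounts 1.6.3 of Subread, DESeq2 1.22.1 and the human build hg19; the gene annotation is not given in the sources used here. No coordinates were used.

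The deposited table lists 26364 genes with 1 value column per library. These signal values, deposited by the authors, are read counts divided by 1 size factor per library, as the values themselves show. Every value above 0 was a whole multiple of the smallest value of its column (100% of values within a tolerance of 0.001 reads), and dividing by that step recovered whole reads and size factors of 0.896 to 1.07. The same table gives the authors' mean over the 6 libraries, their log2 fold changes with standard errors, the Wald score (change over error) and the p-value and adjusted p of each gene, all as deposited by the authors. A rerun of DESeq2 1.42.0 on the recovered reads gave the authors' counts of 700 and 546 called genes, with log2 changes within 3.28e-05. The 10 most abundant genes held 4.43% to 6.32% of the reads of a library. Between 14876 and 15143 of the tested genes had at least 10 normalised counts in each library, and depth was alike in both groups.

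Choices of groups, tests, gene lists, naming rule and most alternatives were made before the data were examined. A count model was foreseen for raw counts; since the table held normalised values, the test foreseen for that case was used. Genes with a value of at least 10 in 3 or more libraries were kept (15346 genes, leaving out 11018). Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 with an intensity trend, siKLF5 against siNC, over all 6 libraries and with no covariate. Two-sided p-values were adjusted by Benjamini-Hochberg and called under 0.05. An exact permutation of 3 against 3 libraries cannot go below an exact p of 0.1, so single genes were tested only by the model that shares the spread between genes. EdgeR 4.0.16 (quasi-likelihood) on the recovered reads was added after seeing the data; it called 300 genes upward and 206 downward of 15299, 485 of them shared with limma.

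The 28 gene lists were matched by symbol, older symbols included. Lists with at least 5 tested members were compared with all tested genes by camera with a preset correlation of 0.01, with camera with an estimated correlation beside it. Fry tested the same lists against no change, not against other genes. Each was adjusted over the lists. The 5 lists named with a camera value below 0.05 were those of desmosomes, basal markers, inflammatory genes, hypoxia and cholesterol synthesis. All 5 were lost with an estimated correlation (adjusted p from 0.513 to 0.863); fry called inflammatory, desmosome and alveolar genes. Mitochondrially encoded genes were not analysed here. A list of 36 secreted liver proteins was added after the values were seen.

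Genes were named by a fixed rule. It took KLF5 and, among genes with an adjusted p under 0.05, a mean of at least 100 and no overlap between groups, the 10 with the largest rise and the 10 with the largest fall. From each list it took up to 4 members with the smallest adjusted p under 0.05, or the 2 most abundant where none passed, and every called KLF or SP gene. A few genes that the rule takes are counted but not reported by name here. Other genes were named after their values were seen, mostly to put names to small counts and to what a list's own adjustment or a left-out library added: CXCL8, IL1B, CXCL5, CXCL3, DSC2, COL17A1, DSP, ITGA6, KRT5, KRT14, KRT17, CDH1, SCARA5, WSCD2, OXGR1, RYR2 and the genes given as passing over a list alone or without a library. PSG4, CYP4F3, MUC20, TUBA1A, KRT6A, KRT8, KRT18, KRT14, KRT17, SAA1, SAA2, ACTB, GAPDH and the histone genes have near-identical relatives or pseudogenes, so their counts are uncertain.

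The fit was tested on simulated counts for the siKLF5 against siNC comparison, drawn from the real means and library sizes, with 200 of 15202 genes changed. Limma called 52 of 100 genes changed by a log2 of 1 and 99 of 100 changed by a log2 of 2, with 16 false calls among 167. EdgeR called 53 and 100 with 15 false calls, and DESeq2 80 and 100 with 58 false calls. Genes were drawn independently, with 1 spread per gene for both groups. Variation shared between genes and the wider spread of the siKLF5 libraries were left out, so these rates need not hold for the real libraries. Alternatives were other scalings (TMM, quantile), DESeq2, limma-voom, other filters, pseudocounts of 10 and 0.5, a replicate block, other thresholds and each library left out. Added after seeing the data were edgeR, removal of each library's smooth trend (span 0.3) on transcript length and GC content of GENCODE transcripts, known for 96.6% of tested genes, and 1 surrogate variable from sva 3.50.0.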

Results

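RNA was profiled by sequencing in Calu-3, an established human lung adenocarcinoma line that grows as a polarised airway-like epithelium. Confluent cells had been transfected with a negative control siRNA (siNC, 3 libraries) or with siRNA against KLF5 (siKLF5, 3 libraries), a zinc-finger transcription factor of epithelial cells. Single-end reads assigned to genes numbered 37081766, 33640814 and 35086661 in siNC replicates 1, 2 and 3 and 39845794, 33462855 and 38305775 in siKLF5 replicates 1, 2 and 3. Between 18628 and 19429 genes had at least 1 read in a library. The labels call the libraries replicates without saying whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values below are the authors' normalised read counts, as mean ± SD over 3 libraries. Log2 changes are siKLF5 against siNC on the log2(value + 1) scale, which understates the change of genes with low counts.

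The comparison asked which transcripts of this airway epithelial line depended on KLF5. KLF5 itself was at 12177, 11231 and 11679 normalised counts in the siNC libraries and at 3086, 3666 and 3666 in the siKLF5 libraries. Its mean fell from 11695 ± 473 to 3472 ± 335 (SD, n = 3), a 3.38-fold lower level (log2 change -1.76, SE 0.12, limma adjusted p = 0.00297). With KLF5 lowered, 289 genes rose and 212 fell among 15346 tested. A change of at least 2-fold was seen for 192 of the genes that rose and 122 of those that fell. Changes of at least 4-fold were found for 55 genes that rose and 5 that fell. These 5 were SCARA5 (-2.78), WSCD2 (-2.38), LEFTY1 (-2.34), OXGR1 (-2.16) and RYR2 (-2.11, all log2). All but LEFTY1 had low counts, with means of 22.4 to 58.7 in siNC and 3.67 to 13.3 in siKLF5 libraries. Of the 6 fits that left out 1 library, SCARA5 and LEFTY1 passed in 3 and the others in 2. In all 501 called genes, the 3 siKLF5 libraries lay on one side of the 3 siNC libraries. That held for 24.7% of the tested genes, where chance gives 10% on average over all splits of the libraries. Genes vary together, so a single split can exceed 10% without an effect of the siRNA. Calling also favours such genes, so neither share is evidence of an effect.

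**Figure D1:**
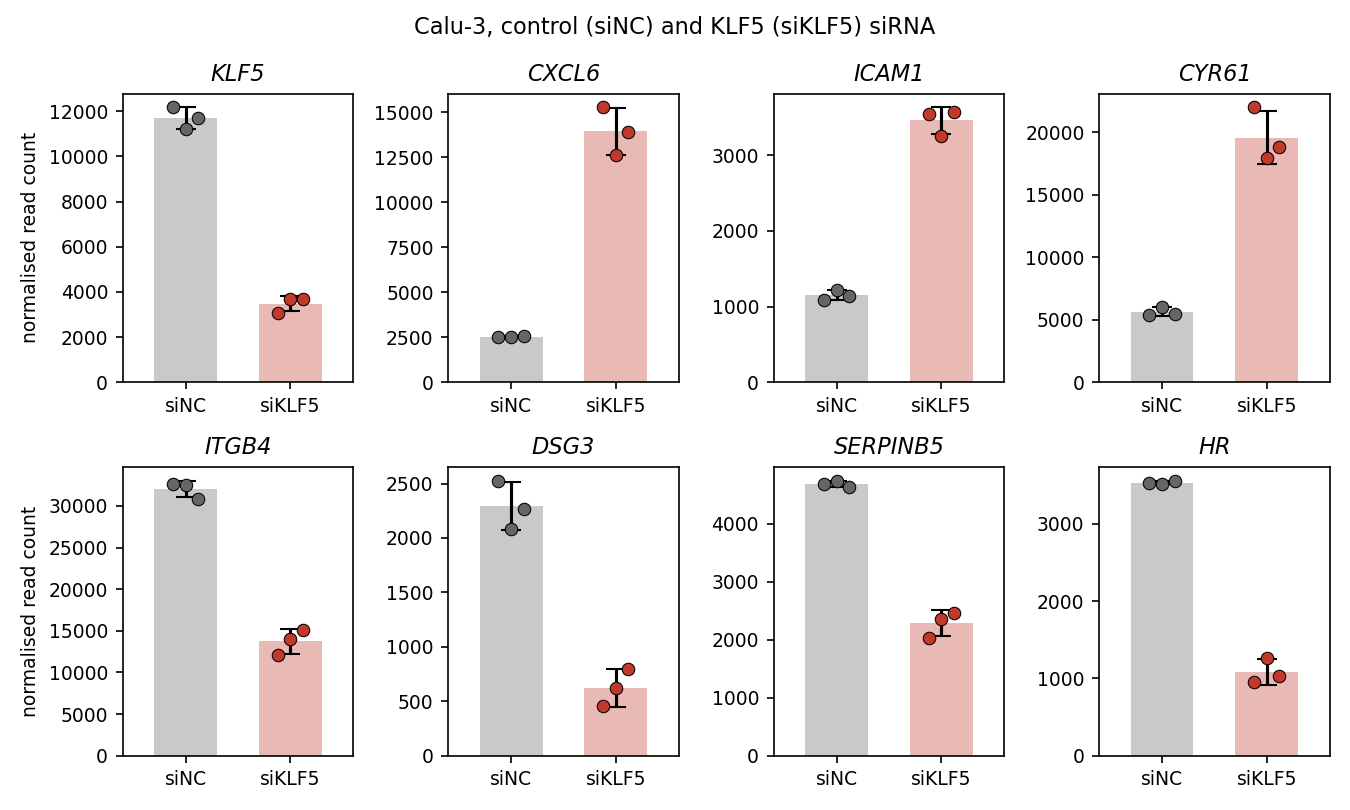
Normalised read counts (vertical axes, linear, from 0) of KLF5 and 7 other called genes in each siNC (grey) and siKLF5 (red) library. Bars are means, error bars SD over 3 libraries and points single libraries; KLF5 lies at 3086 to 3666 in the siKLF5 libraries against 11231 to 12177 in the siNC libraries.

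Among called genes with a mean of at least 100 normalised counts, the largest rise was in SCTR, the secretin receptor, from 11.1 ± 4.03 to 289 ± 173 (log2 change 4.40, SE 0.56, limma adjusted p = 0.0130). Its siKLF5 libraries spread from 103 to 446. PSG4, a pregnancy-specific glycoprotein, followed at 4.07, a value left uncertain by near-identical family members that share reads. Several genes best known from liver secretion were among the 10 largest rises. CRP, the acute-phase C-reactive protein, rose from 17.1 ± 6.86 to 295 ± 102 (log2 change 4.03, SE 0.38, limma adjusted p = 0.00547). The fibrinogen chains FGA and FGB rose by 3.96 and 3.42 (SE 0.34 and 0.25). GC, the vitamin D-binding protein, rose by 2.86, the smallest of the 10. CYP24A1, the 24-hydroxylase that inactivates vitamin D, rose from 46.2 ± 3.73 to 499 ± 160 (log2 change 3.36). SYT12, a synaptotagmin, FAM65C (now RIPOR3) and the pore-forming claudin CLDN2 completed the list at 3.21, 2.88 and 3.07. CLDN2 was the most abundant of these 10 genes, at 727 ± 106 in siNC and 6292 ± 2067 in siKLF5 libraries.

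At the same mean of at least 100, the largest falls were smaller than the largest rises. LEFTY1, a secreted antagonist of Nodal signalling, fell from 199 ± 44.7 to 39.4 ± 12.1 (log2 change -2.34, SE 0.29, limma adjusted p = 0.0126). The uroplakin UPK2 (-1.97), CYP4F3, which inactivates leukotriene B4 (-1.91), and the desmosomal cadherin DSG3 (-1.91) came next. ADGRL3, an adhesion G protein-coupled receptor, and LPCAT2, an acyltransferase of phosphatidylcholine remodelling, fell by 1.79 and 1.77. The actin-binding nebulette NEBL also fell (-1.66). HR, the hairless corepressor, fell from 3534 ± 21.0 to 1084 ± 164 (log2 change -1.72, SE 0.13, limma adjusted p = 0.00326).

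**Figure D2:**
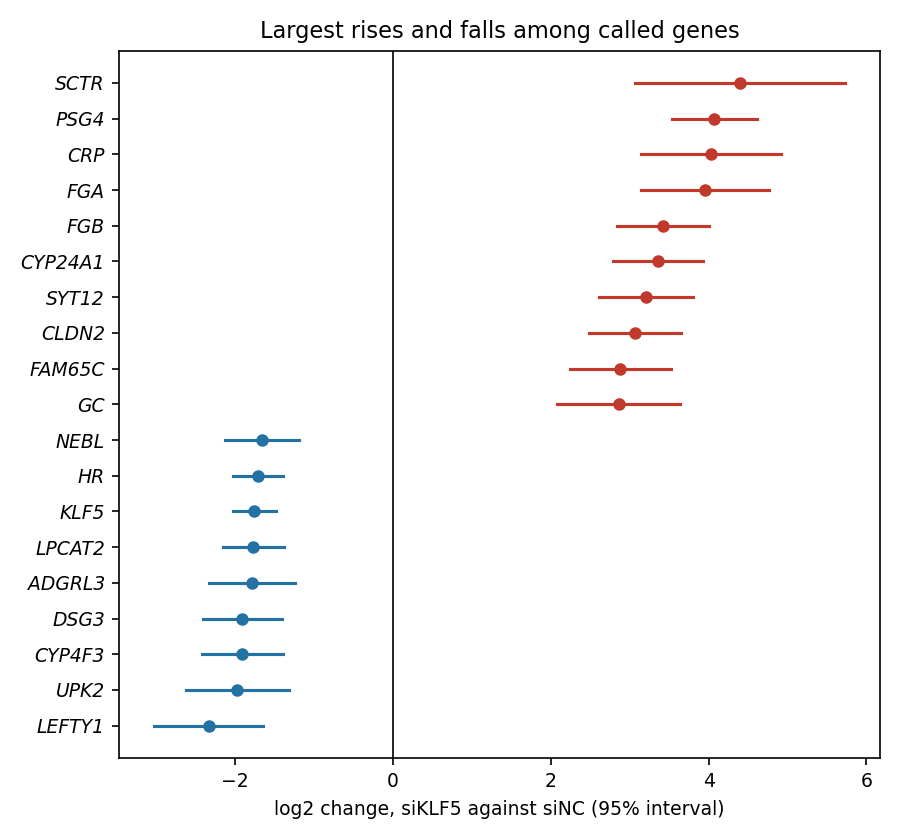
Log2 change of siKLF5 against siNC (horizontal axis) for the 10 genes with the largest rise (red) and 9 of the 10 with the largest fall (blue) by the fixed rule. Points are limma estimates and lines 95% intervals; rises run from 2.86 to 4.40 and falls from -1.66 to -2.34.

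Some genes of desmosomes and hemidesmosomes, which fasten epithelial cells to each other and to the basement membrane, were lower with KLF5 siRNA. Of 20 tested, 6 fell, 0 rose and 14 did not pass; adjusted over the list alone, 10 fell. The hemidesmosomal integrin ITGB4 fell from 32028 ± 997 to 13759 ± 1514 (log2 change -1.22, SE 0.12, limma adjusted p = 0.00673). DSG3 fell from 2293 ± 221 to 625 ± 173. LAMA3, a chain of laminin-332, fell by 1.34 (SE 0.21), and DSC2 and COL17A1 by 1.23 and 0.97. The partner integrin ITGA6 was at -0.88 (SE 0.27, limma adjusted p = 0.162), and the desmoplakin gene DSP at -0.70 (SE 0.31). The median log2 change of the list was -0.63, below that of other genes by camera with a preset correlation (adjusted p = 1.0e-07). With an estimated correlation the adjusted p = 0.513. Fry, which tests a list against no change and not against other genes, gave adjusted p = 0.0348. None of these genes passed without siNC replicate 1, 2 or 3. Without siKLF5 replicate 1, 4 fell (DSC2, DSG3, ITGB4 and LAMA3), without siKLF5 replicate 2, 11 fell and CD151 rose, and without siKLF5 replicate 3, 3 fell, DSG3 and ITGB4 among them.

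Airway basal cell markers had the lowest median log2 change of the fixed lists, at -1.04. Of 13 tested, 2 fell and 11 did not pass: SERPINB5, the maspin serpin, fell from 4690 ± 50.6 to 2287 ± 225 (log2 change -1.04, SE 0.11, limma adjusted p = 0.00825), and the neurotrophin receptor NGFR from 22.6 ± 1.61 to 6.85 ± 2.17. Adjusted over the list alone, 7 fell. The basal keratins had log2 changes of -1.75 for KRT17 (SE 0.54), -1.59 for KRT14 (SE 0.60) and -1.09 for KRT5 (SE 0.37), none of which passed over all genes. For the list, camera gave adjusted p = 1.26e-05 at the preset correlation and adjusted p = 0.531 with an estimated correlation, and fry adjusted p = 0.0606. No basal marker passed without siNC replicate 1, 2 or 3. SERPINB5 alone fell without siKLF5 replicate 1 or 3, and 7 markers fell without siKLF5 replicate 2.

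Inflammatory cytokines and targets of NF-kB held the most called genes of any fixed list: of 33 tested, 10 rose, 2 fell and 21 did not pass. Adjusted over the list alone, 15 rose and 2 fell. The neutrophil chemokine CXCL6 rose from 2529 ± 29.2 to 13948 ± 1316 (log2 change 2.46, SE 0.11, limma adjusted p = 0.00141, the smallest of all genes). The adhesion molecule ICAM1 rose from 1150 ± 69.5 to 3461 ± 175 (log2 change 1.59). The macrophage growth factor CSF1 rose from 71.5 ± 2.93 to 368 ± 54.4, and the monocyte chemokine CCL2 from 7.83 ± 4.01 to 120 ± 29.3 (log2 changes 2.34 and 3.86). CXCL8 and IL1B rose by 1.14 and 2.01. Direction differed within the chemokines, since CXCL5, the most abundant listed gene at 159975 ± 14552 in siNC libraries, fell to 74884 ± 13755 (log2 change -1.11, SE 0.18), and CXCL3 fell by 0.72. The list's median was 0.36, with camera adjusted p = 2.77e-07 at the preset correlation, adjusted p = 0.513 with an estimated correlation, and fry adjusted p = 0.0126. CXCL6, CSF1 and ICAM1 rose in each of the 6 fits that left out 1 library. They alone passed without siNC replicate 3, and with CCL2 they alone passed without siNC replicate 1 or 2 or siKLF5 replicate 3. Without siKLF5 replicate 1, 8 genes rose and CXCL5 fell, and without siKLF5 replicate 2, 16 rose, 2 fell and the median was 0.57.

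Most of the apical junction machinery did not pass the test. Of 33 cell junction genes, 2 rose, 1 fell and 30 did not pass: CLDN2 and CLDN23 rose (log2 changes 3.07 and 0.70), while the barrier claudin CLDN1 fell from 30677 ± 1137 to 18512 ± 2846 (log2 change -0.74, SE 0.14, limma adjusted p = 0.0415). With adjustment over the list alone CTNNB1 and PARD6B were added upward and JUP, plakoglobin, downward. E-cadherin (CDH1) was at 0.16 (SE 0.15). CLDN2 passed without each library in turn, and alone except without siKLF5 replicate 2, where 4 rose and 3 fell.

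Of 29 airway ion and fluid transport genes tested, 1 rose, 1 fell and 27 did not pass. CA12, a membrane carbonic anhydrase, rose from 1355 ± 58.0 to 3449 ± 342 (log2 change 1.34, SE 0.12, limma adjusted p = 0.00468). SLC6A14, an amino acid transporter, fell from 8911 ± 933 to 3251 ± 775 (log2 change -1.48, SE 0.19). Adjusted over the list alone, 3 passed upward (CA12, CFTR and SLC4A2) and 3 downward (SLC6A14, SLC5A1 and ATP12A). CA12 passed without each library but siNC replicate 1, and SLC6A14 without siKLF5 replicate 1 or 2 only; without siKLF5 replicate 2, 4 genes of the list rose and 4 fell. CFTR, the chloride and bicarbonate channel altered in cystic fibrosis, was at 26299 ± 3299 in siNC and 53699 ± 12964 in siKLF5 libraries. Its log2 change of 1.01 (SE 0.21) missed the threshold over all genes (limma adjusted p = 0.0511), while the authors' deposited table gives it an adjusted p of 0.000289.

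Among 31 tested transcription factors of airway epithelium, 3 rose, 1 fell and 27 did not pass. The forkhead factor FOXA1 rose from 583 ± 29.7 to 1125 ± 56.3 (log2 change 0.95, SE 0.11, limma adjusted p = 0.0104). CEBPD and the grainyhead factor GRHL3 rose by 1.18 and 1.37 (SE 0.18 and 0.26). SOX9, a factor of lung progenitors, fell from 18907 ± 1053 to 9929 ± 989 (log2 change -0.93, SE 0.12). When adjusted over the list alone, 4 rose (adding FOXA2) and 4 fell (adding SPDEF, ETV5 and HNF4A). None of the 31 passed without siNC replicate 1, 2 or 3 or siKLF5 replicate 3. Without siKLF5 replicate 1, CEBPD and FOXA1 rose and SOX9 fell, and without siKLF5 replicate 2, 5 rose and 5 fell. No other KLF or SP gene passed among 19 tested, over all genes or over the list alone. The most abundant, KLF6 and SP3, had log2 changes of 0.16 (SE 0.17) and -0.29 (SE 0.23). At an unadjusted limma p under 0.05, 2 of the 19 were higher and 3 lower, and edgeR and the authors' deposited table called 0. With siKLF5 replicate 2 left out, KLF9 and SP6 rose and KLF3, KLF7, KLF12 and KLF13 fell; leaving out any other library gave 0.

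Markers of other airway and alveolar cell types gave few calls. Of 18 secretory markers 1 fell, the antimicrobial enzyme LYZ, from 17289 ± 813 to 10368 ± 858 (log2 change -0.74, SE 0.11, limma adjusted p = 0.0200); adjusted over the list alone, SPDEF was added. None of 13 ciliated markers passed (TUBA1A 0.54, SE 0.17; CAPS -0.21, SE 0.24), with RSPH1 upward over the list alone. None of 8 alveolar markers passed over all genes or over the list alone (CAV1 -0.41, SE 0.12; ABCA3 0.06, SE 0.12). As a list they had camera adjusted p = 0.228 at the preset correlation, adjusted p = 0.786 with an estimated correlation and fry adjusted p = 0.0420, downward. None of 4 tested ionocyte and neuroendocrine markers passed (UCHL1 0.46, SE 0.19), with CFTR upward over the list alone. Of the 6 membrane-bound mucins none passed over all genes; MUC1 (-0.93, SE 0.24) and MUC13 passed downward over the list alone, and MUC20 was at 0.56 (SE 0.25). None of 7 simple epithelial keratins passed (KRT8 0.16, SE 0.19; KRT18 0.15, SE 0.25), with KRT23 upward over the list alone. At an unadjusted limma p under 0.05, ciliated markers numbered 3 upward and 1 downward, alveolar 0 and 2, ionocyte and neuroendocrine 2 and 0, mucins 0 and 2 and simple keratins 1 and 0. Of these lists edgeR on recovered reads called CFTR and KRT23, both upward, and the authors' deposited table also RSPH1 upward and MUC1 and MUC13 downward. Of 7 tested immune and endothelial markers only LYZ, shared with the secretory list, changed, over all genes as over the list alone. LYZ passed without siKLF5 replicate 1 or 2 and with no other library left out. Further genes of these lists passed without siKLF5 replicate 2: LCN2, RSPH1, TPPP3, TUBA1A, CFTR, MUC20, KRT23 and CD68 upward, and CEACAM5, SPDEF, CAV1, RTKN2 and MUC1 downward. CFTR also passed without siKLF5 replicate 1.

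Few matrix and mesenchymal genes passed. Of 27 genes of integrins, matrix and wound repair, 2 rose, 1 fell and 24 did not pass. The matricellular gene CYR61 (CCN1) rose from 5616 ± 360 to 19575 ± 2149 (log2 change 1.80, SE 0.12, limma adjusted p = 0.00297) and the urokinase gene PLAU by 0.80. CTGF (CCN2), of the same family as CYR61, fell from 11361 ± 534 to 6572 ± 738 (log2 change -0.79, SE 0.12). Over the list alone, 5 rose (adding AREG, ITGA3 and ITGB5) and 1 fell. Of 16 mesenchymal genes, FN1, fibronectin, rose from 4811 ± 603 to 10832 ± 1641 (log2 change 1.17, SE 0.16, limma adjusted p = 0.0151), and 15 did not pass; over the list alone 3 rose, CDH2 among them, and THBS1 fell. Of 14 cornified envelope and squamous genes, the protease gene TMPRSS11E rose by 1.75 and SCEL, sciellin, fell from 604 ± 45.6 to 194 ± 35.2 (log2 change -1.64), both also over the list alone. CYR61 passed without each library in turn, FN1 and CTGF without siKLF5 replicate 1 or 2 only, and PLAU and TMPRSS11E without siKLF5 replicate 2 only. SCEL was lost without siNC replicate 1 or 3. Without siKLF5 replicate 2, 7 matrix genes rose and 2 fell, 3 mesenchymal genes rose and THBS1 fell, and KRT16 fell.

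Proliferation genes did not pass in either direction. All 35 tested genes of DNA replication and S phase and all 35 of mitosis missed the threshold over all genes and over the list alone, with medians of 0.10 and -0.06. At an unadjusted limma p under 0.05, 3 replication genes were higher and 0 lower, and 2 mitosis genes were higher and 1 lower; edgeR called 0 of either list and the authors' deposited table FEN1 upward. Their spread between siKLF5 libraries was wide: RRM2 was at 2610, 5974 and 2766 normalised counts and TOP2A at 29642, 79338 and 37686 in siKLF5 replicates 1, 2 and 3. Without siKLF5 replicate 2, 8 mitosis genes fell, FEN1 rose and RRM1 fell. Of 25 p53 targets, PLK3 rose by 0.86 and the cyclin-dependent kinase inhibitor CDKN1A fell from 1107 ± 110 to 561 ± 130 (log2 change -1.004, SE 0.20, limma adjusted p = 0.0460), the latter with no call by edgeR. Over the list alone GDF15 was added upward and FAS and PHLDA3 downward. Of 36 interferon response genes RSAD2 alone passed, falling by 0.60, also over the list alone. Of 26 genes of EGFR ligands and MAPK feedback, EGR1 rose from 1625 ± 118 to 3979 ± 913 (log2 change 1.27) and the receptor gene ERBB3 fell from 19015 ± 291 to 10273 ± 1474 (log2 change -0.90). Over the list alone FOSL1 was added upward and ETV5 downward. CDKN1A, EGR1 and ERBB3 passed without siKLF5 replicate 1 or 2, ERBB3 also without siKLF5 replicate 3, and PLK3 and RSAD2 without siKLF5 replicate 2 only. Without siKLF5 replicate 2, 3 p53 targets rose and 3 fell, 3 interferon genes rose and 4 fell, and 5 genes of EGFR ligands and MAPK feedback rose and 5 fell. Without siKLF5 replicate 3, GDF15 rose.

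Of 25 hypoxia and glycolysis genes 2 rose and 23 did not pass. PFKFB3, a regulator of glycolytic flux, rose from 6148 ± 254 to 12788 ± 2124 (log2 change 1.04, SE 0.14, limma adjusted p = 0.0150), and carbonic anhydrase CA9 by 1.25. Adjusted over the list alone, 5 rose (adding ADM, BNIP3 and NDRG1). The list's median was 0.27, with camera adjusted p = 0.00477 at the preset correlation and adjusted p = 0.835 with an estimated correlation, and fry adjusted p = 0.136. The median was 0.163 without siNC replicate 1 and 0.165 with the length and GC trend removed. Without siKLF5 replicate 2 the camera adjusted p = 0.0867, with 5 genes rising. PFKFB3 alone rose without siKLF5 replicate 1, and no gene of the list passed without siKLF5 replicate 3 or siNC replicate 1, 2 or 3. None of 29 cholesterol and lipid synthesis genes passed over all genes or over the list alone, yet 26 had log2 changes below 0 (median -0.17), with SCD at -0.51 (SE 0.16) and HMGCS1 at -0.13 (SE 0.18). At an unadjusted limma p under 0.05, 5 were lower and 0 higher; edgeR called 0 and the authors' deposited table called 3 downward, INSIG1 and LSS among them. Camera gave adjusted p = 0.00490 at the preset correlation and adjusted p = 0.863 with an estimated correlation, and fry adjusted p = 0.242. Without siKLF5 replicate 1 the median was -0.079 and the preset correlation gave adjusted p = 0.0639. With siKLF5 replicate 2 left out the median was -0.29 and 9 genes fell, and 0 fell when any other library was left out.

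None of 24 unfolded protein response genes (HSPA5 0.21, SE 0.20; HSP90B1 0.23, SE 0.12), 14 replication-dependent histone genes (HIST1H2BK 0.49, SE 0.14; HIST1H1C 0.61, SE 0.21) or 15 housekeeping reference genes (ACTB 0.39, SE 0.18; GAPDH 0.18, SE 0.19) passed, over all genes or over the list alone. At an unadjusted limma p under 0.05 they numbered 0 upward and 4 downward, 2 and 2, and 1 and 0, in that order. EdgeR on recovered reads called 0 genes of these lists, and the authors' deposited table called ASNS, ATF3 and CHAC1 downward and HIST1H2BK upward. When siKLF5 replicate 2 was left out, HSPA5, MANF and HIST1H2BK rose and CHAC1, SLC7A11 and HIST2H2BE fell; leaving out any other library gave 0. The housekeeping genes had a median log2 change of 0.22, with camera adjusted p = 0.0599.

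**Figure D3:**
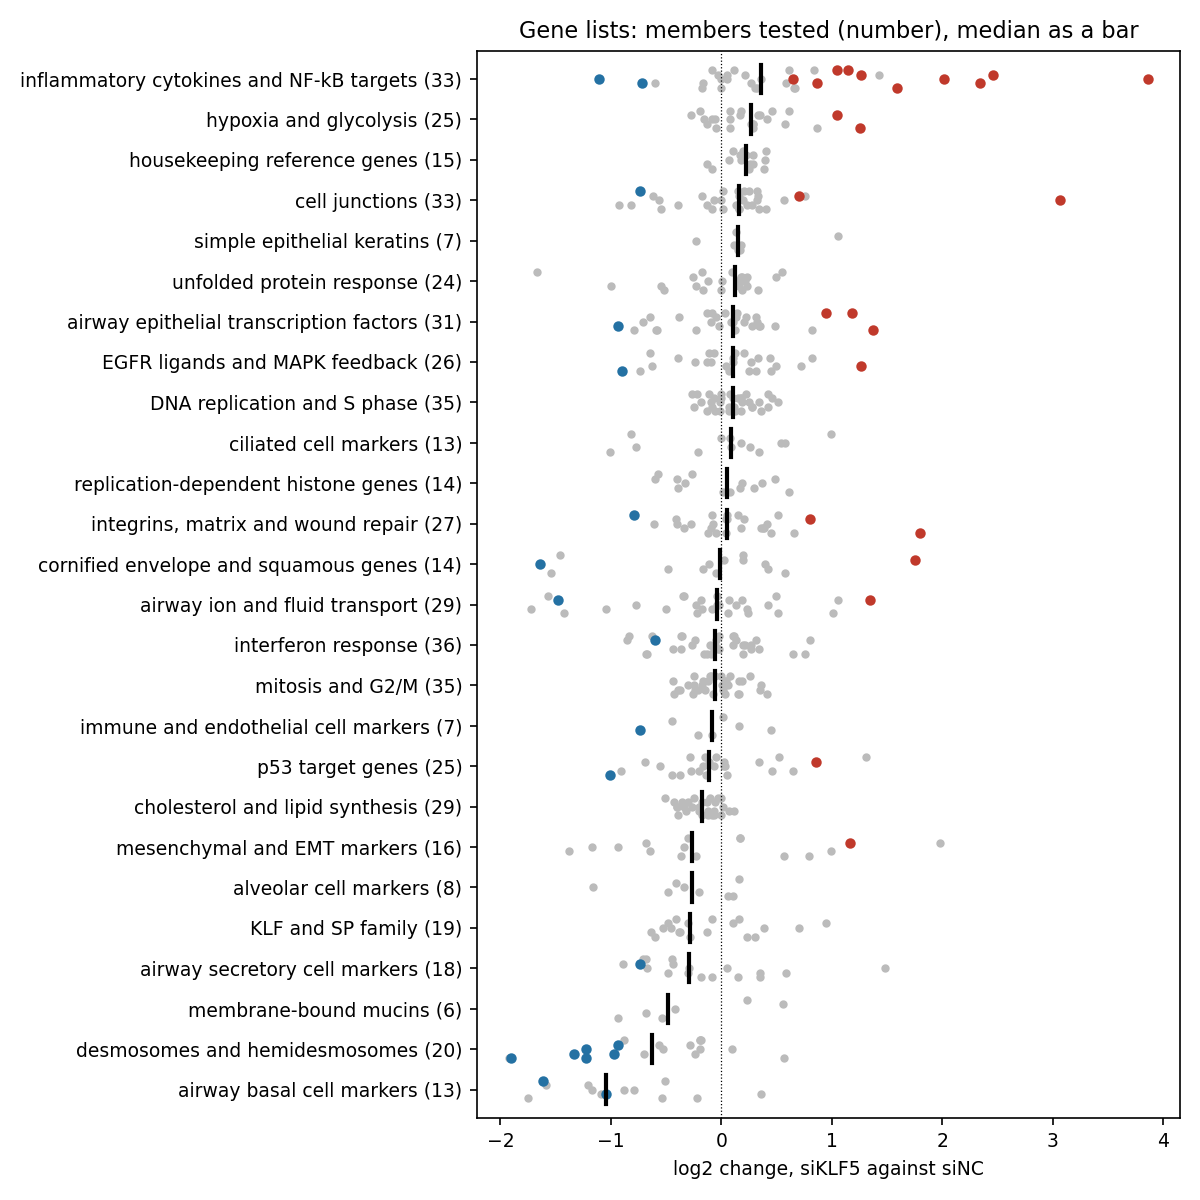
Log2 change of siKLF5 against siNC (horizontal axis) of each tested member of 26 gene lists (rows, number tested in brackets, ordered by median). Points are genes, red where they rose, blue where they fell and grey where they did not pass over all genes, and black bars are medians, from -1.04 for basal markers to 0.36 for inflammatory genes.

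Genes were called by limma with Benjamini-Hochberg adjustment, and 2613 of the tested genes had an unadjusted p under 0.05. The authors' deposited table calls 700 genes upward and 546 downward, and includes all 501 genes called here. The count changed whichever library was left out. It was 34, 59 and 34 without siNC replicates 1, 2 and 3. Without siKLF5 replicates 1, 2 and 3 it was 308, 1981 and 123. All 501 genes kept their direction in these fits, as they had to, since their groups did not overlap. Fewer samples are part of the losses. The same 31 genes passed each time, 13 of the 51 called genes of the naming rule among them. Under a replicate block limma and edgeR each called 0 genes (1420 and 1369 at an unadjusted p under 0.05). The block fits more terms to the same 6 libraries, which by itself makes calls harder, and pairing by replicate number is not known. Calls of CLDN1, CLDN23, NGFR, GRHL3, CDKN1A, RSAD2 and CA9 were also lost under at least 1 other scaling, filter or model. List calls by camera with the preset correlation fell from 5 to 0 with an estimated correlation, and splits of the libraries that mixed both groups called 3 to 8 lists.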

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

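EdgeR, removal of the length and GC trend and the surrogate variable were chosen after seeing the data. KLF5 stayed lower under every alternative, with log2 changes of -1.67 to -1.80, and lost its call only under the replicate block (-1.76, adjusted p = 0.0961; other alternatives ran from 1.76e-33 to 0.0363). The number of called genes was 396 to 556 with TMM or quantile scaling, limma-voom, other filters, other pseudocounts or edgeR, and no scaling moved the median change by over 0.02. DESeq2 on recovered reads and the authors' deposited adjusted p each gave 1246 (700 up, 546 down). An adjusted p under 0.01 left 97 and a change of at least 2-fold left 314, both by their construction. Removing the length and GC trend gave 1647 (911 up, 736 down) and 1 surrogate variable 5391 (2763 up, 2628 down); the cause was not tested, and 474 and 501 of the genes called by limma were called there too. Leaving out 1 library in turn gave 34 to 1981 genes, 31 to 995 upward and 2 to 986 downward, the 2 being KLF5 and HR without siNC replicate 3. All 501 genes kept their direction in each of these 6 fits, which the lack of overlap between their groups had fixed in advance. Deviations of same-numbered libraries correlated at -0.77, -0.81 and -0.26, and no library correlated best with its own number. Such correlations mostly follow the axis shared by both groups, described below, which held 87.7% of the variance within groups. A smaller effect shared by same-numbered libraries could not be seen, so pairing was neither shown nor excluded. With the replicate block limma called 0 genes (0 up, 0 down, and 1420 at an unadjusted p under 0.05) and edgeR 0 (1369 unadjusted). The block fits more terms to the same 6 libraries, which by itself makes calls harder. Lists called by camera numbered 5 to 7 under the scalings, filters, block and left-out libraries, 0 with an estimated correlation and 3 by fry. The DESeq2 and edgeR fits gave no list test.

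Of 51 named genes called, KLF5 included, 0 reversed, which was fixed in advance where 1 library was left out. Of the 50 besides KLF5, 13 to 17 stayed called without 1 siNC library and 27 to 50 without 1 siKLF5 library. Fewer samples are part of that. The replicate block lost all 50. Other calls lost were CLDN1, CLDN23, NGFR, GRHL3 and RSAD2 with no low-value filter, NGFR and CA9 with quantile scaling, CDKN1A with the stricter filter and edgeR, and CLDN23 with the length and GC trend removed (adjusted p at most 0.131). Named genes without a call reversed 7 times, each without 1 library and with values near 0: these were KRT18, ECT2 and HMGCS1 without siKLF5 replicate 1 and CAPS, KLF6, CDC6 and RRM2 without siKLF5 replicate 2. Over the left-out libraries KRT18 ran from -0.070 to 0.37, ECT2 from -0.57 to 0.12, HMGCS1 from -0.29 to 0.038, CAPS from -0.42 to 0.023, KLF6 from -0.012 to 0.31, CDC6 from -0.092 to 0.28 and RRM2 from -0.029 to 0.57. Of the 24 named genes without a call, 17 gained one under at least 1 alternative, 42 times in all: 16 with the surrogate variable, 9 without siKLF5 replicate 2 (such as TOP2A at -0.81 and MUC20 at 0.86), 6 with the length and GC trend removed, and 3 each by DESeq2 and the authors' deposited adjusted p. The other 5 were CFTR under 4 alternatives and CAV1 with quantile scaling. CFTR passed under 9 alternatives and missed under the others (adjusted p from 8.32e-06 to 0.302). Depth of 33462855 to 39845794 reads limited genes with few counts: those below 10 normalised counts in over 3 libraries were not tested.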

Other observations

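The tests of knockdown depth and of hepatocyte RNA, the fit of olfactory receptor reads along the axis and the list of liver proteins below were chosen after the values were seen. Beyond the fixed lists, some genes of proteins that liver secretes into plasma were higher with KLF5 siRNA. Of 24 tested among 36 listed, 7 rose (ALB, AMBP, CRP, FGA, FGB, FGG and GC), 0 fell and 17 did not pass, with a median log2 change of 1.25 and 4 genes below 0; since the list was drawn up from these values, it was not tested against other genes and its count is no independent evidence. The fibrinogen chain FGG rose from 6.01 ± 1.77 to 142 ± 63.1 normalised counts and AMBP from 39.8 ± 3.32 to 195 ± 54.9. The antiprotease gene SERPINA1 was at 14916 ± 2341 and 49695 ± 26384 (log2 change 1.55, limma adjusted p = 0.141) and transferrin (TF) at 25.8 ± 3.85 and 11.3 ± 1.00 (log2 change -1.12, limma adjusted p = 0.0789). Of the 7, CRP, FGA and FGB rose in each of the 6 fits that leave out 1 library, FGG in 5, AMBP in 3 and ALB and GC in 2. They numbered 3, 4 and 4 without siNC replicates 1, 2 and 3 and 7 and 5 without siKLF5 replicates 1 and 3, while without siKLF5 replicate 2, 15 listed genes rose and TF fell. Genes off the list called in each of the 6 fits included the chemokine receptor CXCR4 (2.20), the gap junction gene GJA1 (1.93), the prostaglandin receptor PTGFR (2.85) and the lysyl oxidase relative LOXL2 (1.75, all log2).

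Stray RNA from hepatocytes as the source of this rise is argued against: the added normalised counts of ALB, APOA1, HP and TTR came to 48.0, or 0.0621 of the 773 added by FGA, FGB and FGG, while hepatocytes hold the former in abundance. The trend on transcript length and GC content is argued against too, since the median kept 0.930 of its size once each library's trend was removed, with 9 genes rising. A response of the cells to lowered KLF5 stays as a hypothesis, which these libraries cannot test further; an effect of this siRNA pool on other transcripts was not tested.

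The downward median of desmosome and hemidesmosome genes kept 0.859 of its median when the length and GC trend was removed (-0.54 against -0.63, with 11 genes falling), which argues against that trend as the whole cause. Fewer cells of a basal-like kind within the culture stays open. The 95% interval of DSG3 (-2.41 to -1.41) and that of ITGA6 (-1.52 to -0.24) overlapped. The lower end of ITGA6 minus the upper end of DSG3 was -0.117, so by the rule set beforehand unequal falls of this pair were not shown. Overlap of intervals is no test of a difference, and the difference of this pair was not tested. The interval of the basal marker SERPINB5 (-1.31 to -0.77) lay apart from that of DSG3, so DSG3 and SERPINB5 fell unequally. That comparison was not set beforehand, and how far each gene is confined to basal-like cells is not known here. A smaller number of such cells therefore stays open, and a fall per cell and a loss of cells cannot be told apart here.

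Libraries of both groups spread along 1 shared axis, which held 87.7% of the variance within groups over genes with a mean of at least 100. Scores were -11.4, 18.6 and -7.21 for siNC replicates 1, 2 and 3 and 36.7, -44.9 and 8.17 for siKLF5 replicates 1, 2 and 3, and the median SD of a gene was 0.13 log2 in siNC and 0.27 in siKLF5 libraries. Across 11861 genes, which are not independent replicates, axis loadings followed transcript length (rho -0.64) and GC content (rho 0.57), and log2 changes did so less (rho -0.33 and 0.24). Different depth of the knockdown as the main source of the spread between siKLF5 libraries is argued against. Over 12060 genes the log2 change shared a squared correlation of 0.0397 with the loading on the first axis of these libraries alone (0.0062 to 0.135 without 1 siNC library), where that source needs a high value. Reads from genomic DNA are argued against as the main source of the spread. Each library held 235 to 352 reads over 378 olfactory receptor genes, fewer reads than genes. So few reads per gene could hardly move genes with a mean of at least 100 by a median SD of 0.27 log2. This point was made after the values were seen, and a small part is not excluded. The ratios between libraries did not decide the question. The share of reads in olfactory receptor genes differed 1.18-fold between the end libraries in siNC and 1.5003-fold in siKLF5 (95% intervals for counting error alone 0.993 to 1.41 and 1.27 to 1.78). The bound of 1.5 set beforehand was met in siKLF5. In siNC the upper end of 1.41 lay below it, which by the rule set beforehand counted against this source. That rule was set aside after the values were seen, because the siNC range on the axis was only 0.367 of that of siKLF5. A slope over both groups gave 1.48 between the siKLF5 ends, with a 95% interval from the spread between libraries of 0.856 to 2.56. Removing the length and GC trend took away 47.4% of the sum of squares within groups, short of the 50% set beforehand, so that trend, which RNA quality or library preparation may produce, stays open as part of the spread.

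The 6 libraries allow 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 501 genes and the highest of the others 0. The same fit gave 4985 genes at an unadjusted p under 0.05 when siNC replicate 2, siKLF5 replicate 1 and siKLF5 replicate 3 were set against the rest, against 2613 in the real split. That split parts the libraries by the sign of their scores on the shared axis, so its count restates that structure of the samples and adds no evidence for it. For gene lists the real split gave 5 and the highest of the others 8, and 9 of the 10 splits gave at least 5 lists by camera with the preset correlation.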
